A study of Mus musculus with 4 samples.

How the data were processed

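RNA from mouse liver lysate enriched for mitochondria was depleted of ribosomal RNA (Ribo-Zero Gold), treated with DNase, bisulfite converted in 3 rounds (5 min at 90 °C, then 1 h at 60 °C), and made into small RNA libraries, per the labels' protocols. Reads were processed with Trim Galore and Bismark, per the submitters' processing notes, with versions not given in the sources used here. The notes name the genome build GRCh38, which is a human build, while the samples are mouse. The deposited table holds counts: per the file headers, each mtDNA position has a column of m5C reads and a column of C reads for each of the 4 libraries, made by the authors with no normalization. The m5C count exceeded the C count at 22, 5, 3 and 1 positions of wild type replicates 1 and 2 and knockout replicates 1 and 2, so C holds unmethylated reads and coverage is the sum of both columns. No filter on coverage was seen in the table, which includes positions without reads, and replicates were not pooled.

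Of 5988 positions, 3976 were on the plus strand, 1985 on the minus strand and 27 had no strand. The latter held at most 0.0484% of a library's calls and 0 methylated reads, and were left out of the tests. Positions are printed as the table gives them and run from 7 to 16297. Gene names came from an NCBI table of the mouse assembly GRCm38.p6 (37 mitochondrial genes), and the coding strand of each gene from textbook knowledge. To check that table and file share 1 numbering, the positions without a strand were used: all 27 lie in 2 tRNA genes, and they stay inside tRNA genes only if the annotation is shifted by -1 to 4 nucleotides. A position within a tRNA is counted along the annotated gene, and no structural tRNA numbering was used. Symbols such as TrnM stand for the mitochondrial tRNA gene mt-Tm.

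Methylation level was methylated reads over coverage, in percent. Each cytosine was tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest on methylated and unmethylated counts, with a term for each library, for methylation state and for genotype by methylation state), without a replicate block and with the dispersion fitted without a trend, and p-values were adjusted by Benjamini-Hochberg. A call needed an adjusted p under 0.05 and a difference of group means of at least 10 percentage points. The design fixed before the data were examined asked for at least 10 reads in every library. Because knockout replicate 2 had few tRNA reads, a rule of at least 10 reads summed over each genotype was added after the coverage was seen, and each result says which rule it used. Cytosines a few nucleotides apart share reads and are not independent. Library means were compared by exact permutation tests, two-sided. Exact (Clopper-Pearson) 95% intervals and exact tests were computed with scipy 1.17.1, Newcombe intervals with statsmodels 0.14.6. For 0 methylated reads, the level that 3 counts would give is the upper limit.

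The sites named were set in advance as the called sites (at most 30), uncalled sites with a mean level of at least 20% over the libraries, the highest site of each tRNA gene if at least 5%, the highest site between nucleotides 30 and 38 of TrnM and the highest in mt-Rnr1. The rule gave no coverage for the uncalled and tRNA sites, and 10 reads per genotype were required there. TrnL1 2725, TrnL2 11717, the antisense ND5 pair and mt-Rnr1 911 were named after their values were seen. Site groups were the tRNA variable region window, tRNA outside it, rRNA, mRNA, and antisense or intergenic positions.

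The tests were checked on simulated reads at the coverage of the 482 cytosines with at least 10 reads per genotype, with 20 sites lowered from 70% to 3%, another 20 methylated alike in both genotypes and the rest at background. edgeR recovered 18 of the 20, Fisher's exact test 19 and limma 3.58.1 on log2((methylated + 0.5)/(unmethylated + 0.5)) 0. None of the 3 made a false call, but limma called no site at all. Background sites were drawn without any spread between libraries, so they could hardly reach the 10-point threshold. The spread set for methylated sites was assumed and not fitted to these data. The absence of false calls therefore says little about these libraries. Alternatives were Fisher's exact test, limma, a replicate block, leaving out each library, coverage minimums of 5, 30 and 100, difference thresholds of 5 and 20 points, other methylation thresholds, a window of 18 to 31 nucleotides and fitting and adjustment over tRNA sites alone. The libraries of a genotype differed in coverage across genes by far more than sampling noise (chi-square 3668 with 30 degrees of freedom in wild type), so none was treated as a duplicate.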

Results

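Cytosine methylation was measured by bisulfite sequencing of RNA from mouse liver lysate enriched for mitochondria. Bisulfite converts cytosine to uracil and leaves 5-methylcytosine (m5C) as cytosine, so the share of reads that keep a cytosine is the methylation level of that position. The samples were 2 wild-type libraries and 2 libraries from mice lacking Nsun2, the gene of a methyltransferase known to modify cytosines at the junction of the variable loop and T arm of transfer RNAs. The series title names the question, which is whether NSUN2 introduces m5C into mitochondrial tRNAs. The table listed 5988 cytosines on both strands of mitochondrial DNA (mtDNA), each with methylated and unmethylated reads per library. Summed over positions, these calls came to 89941 and 45471 in wild type replicates 1 and 2, and to 99457 and 453489 in knockout replicates 1 and 2.

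Depth was spread unevenly. Sense cytosines of the 22 mitochondrial tRNA genes took 16.5% and 6.50% of the calls of wild type replicates 1 and 2 and 14.0% of those of knockout replicate 1, but 0.252% of those of knockout replicate 2. In that library 79.9% of all calls fell on positions 763 and 764 in mt-Rnr1, the gene of the small mitochondrial ribosomal RNA, against 20.5% to 22.7% in the other libraries. Values for tRNAs in the knockout therefore came mostly from knockout replicate 1. No label says whether the libraries of a genotype came from separate animals, so the spread between these libraries may be technical. edgeR shares its estimate of that spread over all tested cytosines, most of them with almost no methylated reads. Where knockout replicate 2 has few reads, it adds little to that estimate, and the p-values then do not measure the spread between knockout libraries. Intervals are exact 95% binomial intervals unless another is named. They and the exact tests on reads cover counting error only, because the reads carried no molecular identifiers that the sources used here describe.

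**Figure D1:**
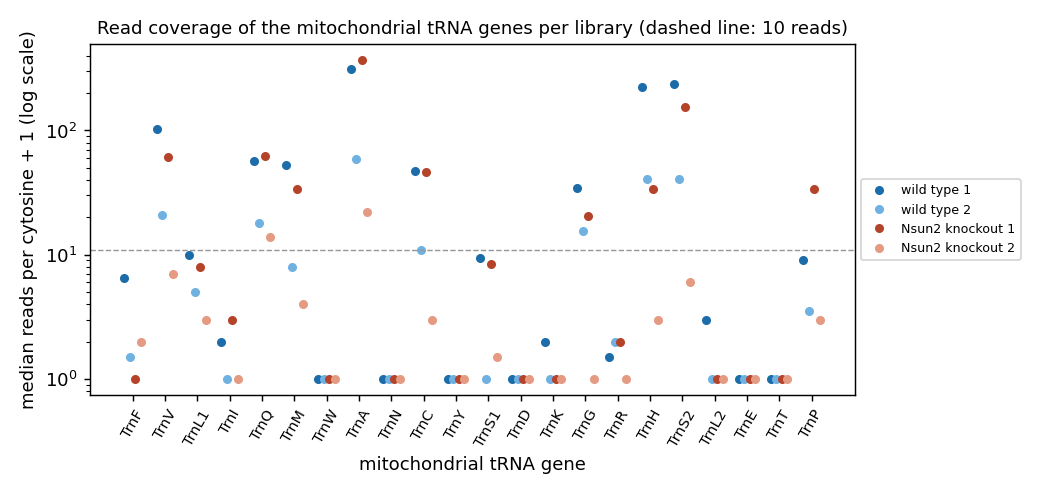
Median reads per sense cytosine plus 1 (log scale) for each of the 22 mitochondrial tRNA genes, with 1 point per library and a dashed line at 10 reads. In TrnM, TrnH and TrnS2 the medians of knockout replicate 2 (3, 2 and 5 reads) lie below the line, while knockout replicate 1 has medians of 33, 33 and 153 reads.

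Unconverted cytosine set the background. Over the 59 cytosines of mitochondrial mRNAs with at least 10 reads in every library, 0.203% of calls were methylated in wild type replicate 1 (interval 0.136% to 0.292%) and 0.0775% in wild type replicate 2 (0.0334% to 0.153%). The shares were 0.0799% in knockout replicate 1 (0.0488% to 0.123%) and 0.0809% in knockout replicate 2 (0.0404% to 0.145%). The median level over these cytosines was 0 in each library. The means of the library shares were 0.140% ± 0.0889 (SD, n = 2) in wild type and 0.0804% ± 0.00077 (SD, n = 2) in the knockout. A two-sided exact permutation test gave p = 1 (where 2 against 2 libraries cannot go below 0.3333).

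The comparison of knockout with wild type asked which mitochondrial cytosines lose or gain methylation without NSUN2. With at least 10 reads summed over each genotype, a rule added after the coverage was seen, methylation fell at 3 cytosines (the rule set in advance gave 0), each in a different mitochondrial tRNA and each 24 or 25 nucleotides before the last annotated nucleotide, and it rose at none. In TrnH, the histidine tRNA, position 11588 (the 43rd nucleotide) was methylated at 99.8% ± 0.307 (SD, n = 2) in wild type, and at 8.33% ± 11.8 (SD, n = 2) in the knockout, where 6 of 38 summed reads were methylated (15.8%, interval 6.02% to 31.3%). In TrnS2, the serine tRNA that reads AGY codons, position 11646 (the 34th nucleotide) was methylated at 67.0% ± 7.71 (SD, n = 2) in wild type and at 10% ± 14.1 (SD, n = 2) in the knockout, where 1 of 156 summed reads was methylated (0.641%, interval 0.0162% to 3.52%). In TrnM, the methionine tRNA, position 3888 (the 44th nucleotide) was methylated at 71.0% ± 21.9 (SD, n = 2) in wild type, and in 0 of 36 knockout reads, which allows a level of up to 8.33%. All 3 sites are in the sense strand of the tRNA, with coordinates of mouse mtDNA as the authors' table gives them.

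These 3 calls came from edgeR's quasi-likelihood test over the 482 cytosines with at least 10 reads summed over each genotype. The differences of group means were -91.4 percentage points at TrnH 11588 (adjusted p = 1.43e-16), -57.0 at TrnS2 11646 (adjusted p = 2.15e-13) and -71.0 at TrnM 3888 (adjusted p = 1.03e-04), with Benjamini-Hochberg adjustment in edgeR. With limma on log2 odds over the same 482 cytosines only TrnH 11588 was called (adjusted p = 7.54e-04), and TrnS2 11646 and TrnM 3888 were not (adjusted p = 0.28 for both). A replicate block in edgeR, a pairing that no label states, kept the calls at TrnH 11588 and TrnS2 11646 but not at TrnM 3888 (adjusted p = 0.0817). The differences in summed reads were -83.8 points at TrnH 11588, -70.2 at TrnS2 11646 and -82.0 at TrnM 3888. Their intervals (Newcombe) ran from -92.2 to -69.1, from -75.4 to -63.8 and from -89.6 to -67.0 points. Group means weigh both libraries of a genotype alike, and at TrnS2 11646 the difference of means, -57.0, lies outside that interval. At each of the 3 sites both knockout libraries lay below both wild-type libraries. The exact permutation p of the library levels was 0.333, the smallest that 2 against 2 libraries allow. With the rule fixed before the data were examined, at least 10 reads in every library, 152 cytosines remained, none of these 3 among them, and 0 passed an adjusted p of 0.05 with a difference of at least 10 points. Of those 152, edgeR gave 3 an unadjusted p under 0.05 and 2 an adjusted p under 0.05. Fisher's exact test on summed reads and limma on log2 odds, run on the same 152, also called 0. Fitted and adjusted over the list alone, the tRNA cytosines gave 0 calls among 15 with 10 reads in every library and 3 among 104 with 10 reads per genotype. Without knockout replicate 1 no site was called among 190 tested, because knockout replicate 2 had 2, 5 and 3 reads at the 3 tRNA sites; without knockout replicate 2 all 3 were called among 463, with 1 library standing for the knockout and the spread taken from wild type alone.

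Per library, the methylated reads at TrnH 11588 were 229 of 230 and 42 of 42 in wild type replicates 1 and 2, and 6 of 36 and 0 of 2 in knockout replicates 1 and 2. At TrnS2 11646 they were 163 of 225 and 24 of 39 in wild type, and 0 of 151 and 1 of 5 in the knockout. The single methylated read of knockout replicate 2 gives 20% with an interval from 0.505% to 71.6%. At TrnM 3888 they were 45 of 52 (86.5%) and 5 of 9 (55.6%) in wild type, and 0 of 33 and 0 of 3 in the knockout. Leaving out wild type replicate 1 took TrnM 3888 below 10 wild-type reads and left 2 of the calls.

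**Figure D2:**
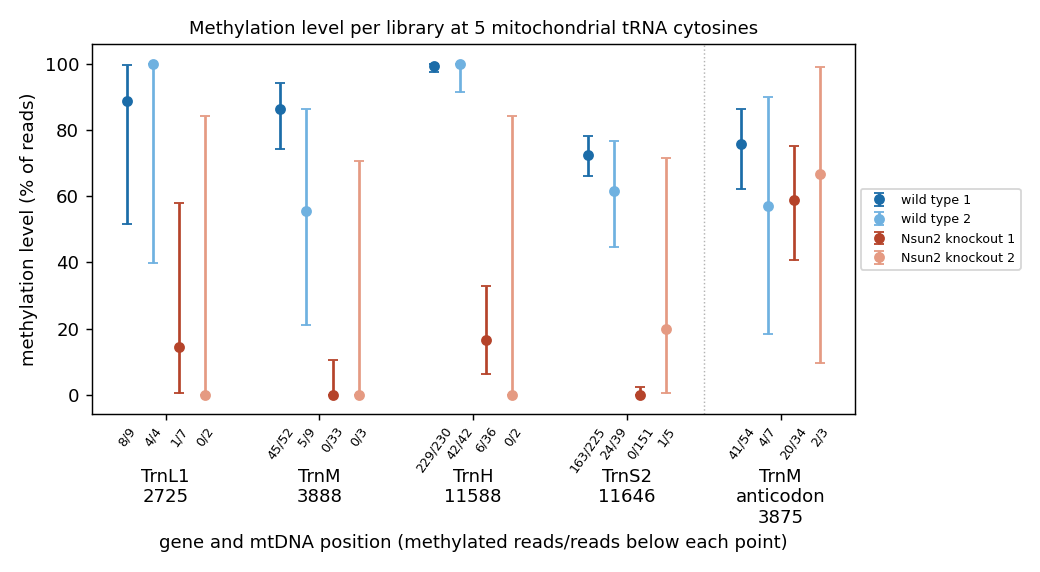
Methylation level (percent of reads) at 5 mitochondrial tRNA cytosines in each of the 4 libraries, with exact 95% binomial intervals and the methylated and total reads under each point. At TrnM 3888, TrnH 11588 and TrnS2 11646 both wild-type libraries lie at 55.6% or above and both knockout libraries at 20% or below, whereas at TrnM 3875, in the anticodon, all 4 libraries lie between 57.1% and 75.9%.

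A site in TrnL1, the leucine tRNA that reads UUR codons, had the same position relative to the tRNA end but fewer reads, and was picked after its values were seen. Position 2725 (the 50th nucleotide, 25 before the last) was methylated in 8 of 9 and 4 of 4 wild-type reads, and in 1 of 7 and 0 of 2 knockout reads. Summed over libraries this is 92.3% (interval 64.0% to 99.8%) against 11.1% (0.281% to 48.3%). With at least 5 reads per genotype (681 cytosines), edgeR gave it an adjusted p of 1 and Fisher's exact test on the summed reads an adjusted p of 0.0231. The neighbouring cytosines 2723 and 2724 of TrnL1 had 0 methylated reads of 12 and 13 in wild type, and 1 of 9 and 0 of 9 in the knockout, so the knockout level at 2725 (1 of 9) equals that at 2723. In TrnL2, the other leucine tRNA, 2 of 2 reads of wild type replicate 1 were methylated at position 11717 and no other library had a read there.

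The variable region window was taken as 20 to 29 nucleotides before the last annotated nucleotide of each tRNA. It held 23 listed cytosines in 13 tRNA genes, of which 8 in 5 genes had at least 10 reads per genotype. The 3 lower sites were among those 8. The other 5 (TrnV 1073, TrnG 9436, TrnH 11585, TrnS2 11643 and TrnS2 11647) had 61 to 284 wild-type reads and 27 to 160 knockout reads, with at most 0.957% methylated in wild type and 0 in the knockout. Only TrnH (2) and TrnS2 (3) had more than 1 of these cytosines, and in each of them 1 was called. In TrnS2 the cytosine next to the called one, 11647, was methylated in 2 of 260 wild-type reads. Over the 8 cytosines the mean level was 29.9% ± 3.85 (SD, n = 2) in wild type and 2.29% ± 0.295 (SD, n = 2) in the knockout (two-sided exact permutation p = 0.333, the smallest possible). The small knockout SD does not show agreement between the libraries. The 2.08% of knockout replicate 1 came from TrnH 11588 alone (6 of 36 reads). The 2.5% of knockout replicate 2 came from 1 of 5 reads at TrnS2 11646. Under the rule of 10 reads in every library only TrnV 1073 remained, with 0.585% ± 0.827 (SD, n = 2) in wild type and 0 in the knockout (exact permutation p = 1). The window cytosines of 4 tRNA genes, TrnW, TrnN, TrnY and TrnT, had no read in any library, so methylation there was not detectable at this depth.

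The cytosine in the anticodon of TrnM served as the site of another enzyme: NSUN3 is known to methylate the wobble position of the mitochondrial methionine tRNA. Position 3875, the 31st nucleotide of TrnM and the highest site between nucleotides 30 and 38, was methylated in 41 of 54 and 4 of 7 wild-type reads and in 20 of 34 and 2 of 3 knockout reads. The means were 66.5% ± 13.3 (SD, n = 2) in wild type and 62.7% ± 5.55 (SD, n = 2) in the knockout, a difference of -3.79 points (edgeR adjusted p = 1). The summed reads gave 73.8% against 59.5%, and the interval of their difference ran from -32.8 to 4.41 points (Newcombe), so a moderate decrease is not excluded. The difference of means turned to 5.60 points without wild type replicate 1 and to 0.132 points without knockout replicate 1. On the same tRNA molecule, position 3888 lay 13 nucleotides further on and had 0 of 33 reads methylated in knockout replicate 1.

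The 12S rRNA, the product of mt-Rnr1, is a known target of NSUN4. Its cytosine with the highest level averaged over the 4 libraries, among those with at least 10 reads in every library, was position 753, a rank that owes much to knockout replicate 2. It was picked by its level and is not shown here to be the site of NSUN4. It had 0.118% and 0.0782% methylated reads in wild type replicates 1 and 2, and 0.104% and 0.424% (interval 0.353% to 0.506%) in knockout replicates 1 and 2, the last above the mRNA background of 0.0809% in that library. The edgeR test gave it an adjusted p of 1. Fisher's exact test on summed reads gave 5.4e-05, with 123 of the 130 methylated knockout reads in knockout replicate 2. Only 30 of the 188 sense cytosines of mt-Rnr1 had at least 10 reads per genotype, and position 911 had 1 read in wild type and 4 in the knockout, so most of this rRNA was not tested.

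Outside the tRNA window no cytosine was called among those with at least 10 reads per genotype. These were 96 tRNA cytosines outside the window, 77 in ribosomal RNAs, 175 in mRNAs and 126 antisense to a gene or between genes. The highest wild-type mean among the mRNA cytosines was 2.14%, and the highest knockout mean 0.481%. Of the 22 tRNA genes, 10 had no cytosine with enough reads in both genotypes. At the 10-point threshold on the difference, a pair of antisense sites in ND5, positions 13168 and 13176 on the minus strand, was not called although each passed the adjusted p. Position 13168 had 7.57% ± 0.654 (SD, n = 2) in wild type and 0.727% ± 0.440 (SD, n = 2) in the knockout (edgeR adjusted p = 0.00114 over the 152 cytosines). Position 13176 had 5.62% ± 2.08 (SD, n = 2) and 0.477% ± 0.264 (SD, n = 2) (edgeR adjusted p = 0.00257). Over the same 152 cytosines neither position passed with limma on log2 odds (adjusted p = 0.43 for both). Neither passed with a replicate block in edgeR (adjusted p = 0.157 at 13168 and 0.212 at 13176). At both positions each knockout library lay below each wild-type library, and leaving out any library except wild type replicate 2 took both adjusted p-values above 0.05 (0.0746 to 0.785), while the differences in those fits stayed at -7.15 to -6.38 points at 13168 and -5.33 to -3.67 at 13176 (-6.84 and -5.14 with all libraries).

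At the level of single genotypes, 2 cytosines (TrnH 11588 and TrnS2 11646) had at least 10 reads and a level of at least 10% in both wild-type libraries, and 0 did so in both knockout libraries. Knockout replicate 2 had 2 to 5 reads at TrnM 3875, TrnM 3888, TrnH 11588 and TrnS2 11646, too few to count there. At TrnM 3888 and TrnS2 11646 knockout replicate 1 also failed on level, with 0 of 33 and 0 of 151 reads methylated. In knockout replicate 1 alone 2 cytosines passed both thresholds (TrnM 3875 and TrnH 11588), so their absence follows from coverage. With reads summed over the genotype, 5 cytosines reached 10% in wild type (TrnL1 2725, TrnM 3875, TrnM 3888, TrnH 11588 and TrnS2 11646) and 2 in the knockout (TrnM 3875 and TrnH 11588).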

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

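Both results here were picked out because methylated reads appeared at positions with too few reads for any comparison of the report, and no explanation was tested. At position 911 of mt-Rnr1, nucleotide 842 of the gene, 3 of 4 reads of knockout replicate 1 were methylated (75%, exact 95% interval 19.4% to 99.4%). Wild type replicate 1 had 0 of 1 read methylated there, and the remaining libraries had no read. In wild type replicate 1, all 15 successive plus-strand cytosines with reads between positions 14620 and 14673, in CYTB, carried a methylated call. CYTB had a median of 0 and a maximum of 11 reads per sense cytosine in that library. Such calls cannot tell m5C from cytosine that was not converted.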

How the results depend on the processing

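Alternatives with a coverage rule per genotype were chosen after seeing the data; the others were planned. The count of lower sites, 0 as planned, became 1 at a coverage minimum of 5 (TrnS2 11646), 2 with a difference threshold of 5 points (the antisense ND5 pair), and ran from 0 to 2 when single libraries were left out, 2 being the value without knockout replicate 2. At 10 reads per genotype it was 3 with edgeR, 3 with Fisher's exact test, 1 with limma, 2 with the replicate block, and 0 to 3 when single libraries were left out; it was 3 when fitted over tRNA sites alone; at 5 reads per genotype it was 3 with edgeR and 4 with Fisher's exact test. The count of higher sites was 0 in every setting run. The count of methylated sites in wild type, 2 as planned, was 4 at a coverage minimum of 5, 0 at a minimum of 100, 5 with summed reads, and 2 to 4 without single libraries. In the knockout it was 0 as planned, 2 with summed reads and 0 to 2 without single libraries. The knockout minus wild type difference of the window mean, -0.585 points as planned, was -0.144 with a window of 18 to 31 nucleotides, -14.5 at a coverage minimum of 5, -27.6 at 10 reads per genotype and -27.2 when weighted by coverage there, with -21.6 to 0 when single libraries were left out (-21.6 without knockout replicate 2). Median background, 0 as planned, was 0.244% and 0.0586% as a mean in wild type and knockout, and 0.0893% in wild type at a coverage minimum of 30. The difference at TrnM 3875 ran from -13.2 to 5.60 points without single libraries. A coverage minimum of 30 or 100 left no cytosine in the window and no value at TrnM 3875. The alternatives planned for a table without reads did not apply.

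Replicate numbers 1 and 2 are shared by both genotypes, but no label says that they pair the samples. The deviations of same-numbered libraries correlated at 0.256 (log2 odds) and 0.0319 (level) over the 152 cytosines, and at 0.115 and -0.238 over the 482, so the data give no clear pairing. With the replicate block the planned count stayed at 0 and the count at 10 reads per genotype was 2, with an adjusted p of 0.0817 for TrnM 3888. TrnH 11588 kept its call in each of the 10 alternatives that could test it, with adjusted p of at most 7.54e-04. TrnS2 11646 kept it in 10 of 11 and TrnM 3888 in 6 of 8, with an adjusted p of 0.28 for both under limma. All of these alternatives kept knockout replicate 1, which held most knockout reads at these sites, so they do not test the calls without it. The antisense pair kept its adjusted p in 10 of 20 alternatives at 13168 and in 9 of 20 at 13176.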

Other observations

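The tests in this part were chosen after the results were seen, except the planned edgeR fits that leave out a library, and the exact tests take each read as a separate molecule, which the table cannot show. Coverage of TrnH, the histidine tRNA, was lower in knockout replicate 1 than that of its neighbour TrnS2. Reads at TrnH 11588 made up 50.6% and 51.9% of the reads at TrnH 11588 and TrnS2 11646 together in wild type replicates 1 and 2, against 19.2% in knockout replicate 1 and 28.6% (2 of 7 reads) in knockout replicate 2. TrnP, the proline tRNA, differed in the other direction, with a median of 8 reads per cytosine in wild type replicate 1 and 32.5 in knockout replicate 1. Its medians in wild type replicate 2 and knockout replicate 2 were 2.5 and 2 reads.

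The low TrnH coverage in knockout replicate 1 may reflect uneven recovery of tRNAs, a single library or the genotype. Lower total depth does not explain it. That library had 99457 calls, 13916 of them in tRNAs, against 89941 and 14856 in wild type replicate 1. The median coverage of TrnH in knockout replicate 1 was -2.73 on the log2 scale relative to wild type replicate 1 (0.5 reads added to both medians). The other 11 tRNA genes with a median of at least 5 reads in wild type replicate 1 had a median of -0.341 with an SD of 1.30. They ranged from -3.58 in TrnF, with a median of 5.5 reads in wild type replicate 1 and 0 in knockout replicate 1, to 1.96 in TrnP. TrnH lies within 2 SD of their median, with the low-read TrnF counted in that SD, so a recovery that varies between tRNAs stays open. Whether it is a property of that library alone stays open: in knockout replicate 2 Fisher's exact test of the TrnH share against wild type gave p = 0.282 (1.59e-14 for knockout replicate 1), and 7 reads are too few to decide. An effect of the genotype on the amount of this tRNA was not tested.

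The methylation left at TrnH 11588 in knockout replicate 1, 6 of 36 reads, is a pattern of its own, since TrnS2 11646 had 0 of 151 and TrnM 3888 had 0 of 33 in the same library. Wild-type RNA mixed into the library would spread methylated reads over the sites as in wild type replicate 1, where 46.7% of methylated reads at the 4 sites (TrnL1 2725 included) were at TrnS2 and TrnM; 0 of 7 were found there (exact one-sided binomial p = 0.0122). With 7 reads, 6 of them at 1 site and possibly copies of fewer molecules, this leaves mixing open. Of the other 12 cytosines of TrnH, 2 of 397 calls were unconverted in that library (Fisher's exact p = 5.45e-06). If the 6 methylated reads were copies of 1 molecule, with all other reads still counted singly, that p would be 0.202. This is an extreme case, but which reads are copies is unknown, so incomplete conversion stays open too. Also open, as a hypothesis not tested here, is that another enzyme or another RNA may contribute at this site. Knockout replicate 2 had 2 reads there and cannot add to this.

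The antisense pair in ND5, 13168 and 13176 on the minus strand, 8 nucleotides apart, had lower levels in the knockout. The next minus-strand cytosines, 13192 and 13209, had 0 of 401 wild-type calls methylated against 42 of 654 at the pair (Fisher's exact p = 2.14e-09). This p-value is too small, because a read is counted at each cytosine it covers and the pair was picked after its values were seen. These counts argue against poor conversion in wild type that extends to the neighbours, but not against poor conversion at the pair alone. Dilution by extra short reads does not account for knockout replicate 1, whose coverage at 13168 was 1.1 times that at 13192, as against 1.15 in both wild-type libraries; in knockout replicate 2 the ratio was 36.5, above the 20.8 that would bring the wild-type level down to that library's, so dilution could account for the low level there. What remains is knockout replicate 1 (3 of 289 reads at 13168, Fisher's exact p = 9.07e-05 against the summed wild-type reads, a comparison of these libraries only). With that library alone as the knockout the differences were -6.53 points at 13168 and -4.95 at 13176, with edgeR adjusted p-values of 0.383 and 0.785 (Benjamini-Hochberg). A loss of methylation at the pair stays open, since 1 library gives no spread for the knockout, and so does poor conversion at the pair alone.

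At mt-Rnr1 753 the level of knockout replicate 2, 0.424%, lay above the 0.0782% to 0.118% of the other libraries.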
